A study of Lactococcus lactis subsp. lactis with 2 samples.

How the data were processed

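Gene expression was measured in Lactococcus lactis subsp. lactis strain CHCC2862, a lactic acid bacterium, on 2 two-colour microarrays. The culture grew in M17, a rich broth for lactococci, with 0.5% lactose and 5 mg/L hemin under agitation at 170 rpm, per the labels' protocols. Hemin supplies the haem that this species cannot make and needs for respiration. The labels give the optical density (OD) of each RNA sample. The RNA of OD 2.5 was labelled with Cy3 and served as the reference on both arrays, and the RNA of OD 5.6 or of OD 6.4 was labelled with Cy5, per the labels. Total RNA was stabilised at sampling and purified on columns after lysis with lysozyme, mutanolysin and proteinase K, and 10 ug was copied into cDNA from random nonamers and labelled after synthesis, per the labels' protocols. The array design, the scanner, the background correction and the normalization are not given in the sources used here.

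The deposited table holds 1 value for each of 1674 features and each array, as the authors processed it. The values were read as log2 ratios of the 2 channels, on the authors' normalization. The log base is not stated with the deposited values. They run from -5.66 to 7.85, which excludes a linear scale. As log10 values the largest would be a ratio of 7.01e+07, above the 65536 that a 16-bit scanner can span. Natural logs are not excluded, and a value of 1 would then be 2.72-fold instead of 2-fold. The direction is not stated either. It was taken as Cy5 over Cy3, the later sample over OD 2.5, which the dye labels and the series design make likely. Scanner intensities were not used here, so no background level, saturation or dye bias could be examined, and the depth of measurement behind each ratio is unknown. With OD 2.5 in Cy3 on both arrays and no dye swap, dye and density cannot be told apart in either ratio. Precision is limited by the number of arrays, which is 1 for each OD.

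The OD 5.6 column holds 1627 values and the OD 6.4 column 1658. No feature name occurs more than once, so no averaging was needed. Feature names were used as deposited, and no sequence or coordinate of a probe was used here. Of the 1674 names, 312 (18.6%) matched a symbol or synonym in the RefSeq gene table of L. lactis subsp. lactis 14B4, assembly ASM317683v1. Positions were therefore not used. Nearly identical gene copies can share signal on an array, and their ratios are uncertain to that extent. Whether copies such as those of arcC and ackA are that alike was not examined.

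With 1 array for each OD no test of a difference between densities exists, so no p-value is given. Features are counted at or past a log2 ratio of 1 in size. OD 6.4 was compared with OD 5.6 by the difference of the log2 ratios of a feature on the 2 arrays, over the 1611 features with both values, in which the shared reference cancels as far as it is the same RNA. The counting and the random lists were tested on simulated data. With 1627 simulated features, noise of 0.3 (SD) and changes of 1.5, 92% of the raised features and 90% of the lowered features passed for the OD 5.6 comparison, and 0% of unchanged features did. The noise of the simulation is an assumption, since the arrays give no estimate of it. At noise of 0.3 the 0% follows from the threshold of 1. It checks the counting only and does not say how many counted features are unchanged.

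Before the data were examined, 25 gene lists were fixed, together with the design, the alternatives and the rule for named genes. The prophage list matched no feature, and the other 24 lists matched 461 features. A list is described by its median with a 95% bootstrap interval over its genes (2000 draws), by its counts at or past 2-fold, and by the percentile of its median among 10000 random lists of the same size. Matching on expression level was not possible without intensities. Genes are not replicates and genes of an operon move together, so intervals and percentiles describe these arrays and are no tests. The named genes are the 10 highest and 10 lowest features of each comparison past 2-fold, the 2 highest and 2 lowest members of each list on each array, and 26 preset genes, of which lacG, ccpA and purC had no feature of that name. Of the list members that the rule selects, only examples are given, and the values of 1 gene are not reported here. Where other genes are named, they were chosen after their values were seen.

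Alternatives were centring each array on its median, centring and also scaling both arrays to one median absolute deviation, thresholds of 1.5-fold and 3-fold, only features on both arrays, list means and, for the agreement of the arrays, Spearman's rho and a version without the largest 5% of features. Runs of neighbouring genes could not be drawn from the reference annotation because too few names matched. Runs in alphabetical order of name, list medians with the arrays scaled, a list with the features of prefix p- and counts without the most repeated value were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.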

Results

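Transcript levels of L. lactis subsp. lactis CHCC2862 growing with haem and agitation were followed from OD 2.5 to OD 5.6 and OD 6.4. By the title of the series, the samples form a respiratory time course of entry into stationary phase and beyond. Each of the 2 later samples was hybridised on 1 array against the OD 2.5 sample. There were no replicate arrays, so no value below has a replicate error and none of the differences was tested. The median log2 ratio was 0.014 at OD 5.6 (SD over features 1.17) and -0.239 at OD 6.4 (SD over features 1.98). Values are given as deposited and are to be read against these medians, which differ by -0.253. The one internal measure of scatter is the spread among features that share a 3-letter gene stem. Its pooled SD was 0.955 over 1198 features at OD 5.6 and 1.45 over 1223 features at OD 6.4, real differences between such genes included. A single gene at 2-fold is therefore within about this pooled scatter. The pool includes the many stems that begin with y, and it is no estimate of measurement error.

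The first comparison asked which transcripts differed at OD 5.6 from OD 2.5. Of the fixed lists, ribosomal proteins (median -2.23) and fatty acid synthesis (-1.499) had the lowest medians, and the arginine deiminase pathway (1.36) and oxidative stress (1.28) the highest. In all, 266 of 1627 features (16.3%) were at least 2-fold higher and 266 (16.3%) at least 2-fold lower. The highest 10 were yxbF (7.85), yxbD (7.35), ribB (6.85), ribG (6.34), ribA (6.03), ynaE (5.52), mycA (4.71), ribH (4.66), yxbE (4.35) and yteE (3.94). The rib genes encode enzymes of riboflavin synthesis. The fifth rib feature, ribC, stood at -1.68.

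Of 55 ribosomal protein genes, 48 were at least 2-fold lower at OD 5.6 and none was at least 2-fold higher. Their median was -2.23 (95% bootstrap interval over genes -2.40 to -2.06), below all 10000 random lists of that size. The lowest were rplL at -3.86, for the L7/L12 protein of the ribosomal stalk, and rpmGB at -3.13. The highest were rpmGC at 0.19 and rplI at 0.13. Of the 10 lowest features on the array, 6 were ribosomal protein genes, and the others were ykjA (-3.22), blt (-2.98), yuaE (-2.97) and ptnAB (-3.21), a subunit of the mannose and glucose phosphotransferase system. In the RNA polymerase list 7 of 10 genes were at least 2-fold lower (median -1.19), among them rpoB at -2.04 and rpoA at -1.98, while the main sigma factor gene rpoD stood at 0.60. Translation factors and tRNA synthetases were mixed, with 10 of 29 at least 2-fold lower and 1 at least 2-fold higher. Within them infB, for initiation factor IF-2, stood at -2.35, and tuf, for elongation factor Tu, at 0.28.

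Fatty acid synthesis had 12 of 15 genes at least 2-fold lower, none at least 2-fold higher and a median of -1.499 (interval -1.81 to -1.10). The lowest members were rmaG at -2.31, a MarR-type regulator gene, and fabH at -2.14, for the enzyme that starts chain elongation. The arginine deiminase pathway breaks arginine down to ornithine, ammonia and ATP. Its list also holds genes that are not enzymes of the breakdown, such as the regulator genes argR and ahrC. The list had 6 of 10 genes at least 2-fold higher and none at least 2-fold lower (median 1.36, interval 0.651 to 1.84). Its highest members were arcA at 2.46, for arginine deiminase, and arcB at 2.30, for ornithine carbamoyltransferase. Oxidative stress genes had 7 of 11 members at least 2-fold higher (median 1.28, interval 0.287 to 2.05), with ahpC, for alkyl hydroperoxide reductase, at 2.66, gshR, for glutathione reductase, at 2.15 and sodA, for superoxide dismutase, at 1.20. No member of that list was at least 2-fold lower.

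Among the genes of oxygen use, noxE, for a water-forming NADH oxidase, stood at 3.01 and qor at 2.64. Of the genes of the cytochrome bd oxidase, the terminal oxidase of the respiratory chain, cydA stood at -1.25, past 2-fold, and cydB at -0.85, short of it. The list as a whole had 2 of 9 genes at least 2-fold higher and 2 at least 2-fold lower. Its median was -0.85 and its mean 0.15. The 14 menaquinone and haem genes had a median of 0.060, 1 of them (hemN, -1.32) at least 2-fold lower, and menB stood at 0.056. ATP synthase genes lay between -0.83 (atpE) and 0.69 (atpB). Glycolytic genes had a median of 0.69 with 4 of 14 at least 2-fold higher, among them gapB at 1.35 and pyk at 1.24, and 1, ldhX at -2.10, at least 2-fold lower. The lactate dehydrogenase gene ldh stood at 0.11. In the pyruvate list 4 of 18 genes were at least 2-fold higher, led by poxL (2.93), for pyruvate oxidase, and pfl (2.58), for pyruvate formate-lyase, and 3 at least 2-fold lower, led by adhE (-1.28). The other preset genes of this list stayed under 2-fold, with aldB at 0.92, als at 0.37, pdhA at 0.23 and butA at 0.030.

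Purine genes were on the high side at OD 5.6, with 6 of 19 at least 2-fold higher and 2 at least 2-fold lower (median 0.77, interval 0.194 to 1.22). The highest were purE at 1.84 and purH at 1.73, and the lowest were the salvage genes apt at -1.57 and hprT at -1.28. Pyrimidine synthesis had 3 of 13 genes at least 2-fold lower and none at least 2-fold higher, with pyrE at -1.60 and pyrC at -1.47. The list of arginine, glutamate and glutamine synthesis had 4 of 10 genes at least 2-fold higher, argD (2.22) and glnA (1.601) the highest, and none at least 2-fold lower (median 0.081). In the list of other amino acid synthesis 6 of 45 genes were at least 2-fold higher, led by cysK (2.06), and 5 at least 2-fold lower, led by aroH (-1.97). The peptide list had 4 of 25 at least 2-fold higher and 2 at least 2-fold lower. The latter were ctrA at -2.48 and dtpT at -2.12, the latter for the di- and tripeptide transporter, while oppA stood at 0.28 and codY at 1.26. Of 47 other carbohydrate genes, 1 (gntR, 1.78) was at least 2-fold higher and 8 at least 2-fold lower, ptnC at -2.86 among them. The heat shock list had 2 of 14 genes at least 2-fold higher, hslB at 1.82 and htrA at 1.28, with groEL at 0.50, dnaK at 0.003 and clpE at 0.99. The cell wall, DNA replication and metal uptake lists had medians of 0.071, -0.11 and 0.18. With both arrays centred and scaled to one median absolute deviation, 5 of 9 respiration genes were at least 2-fold lower in place of 2 (median -1.17). The same scaling gave 7 higher in place of 4 in both the glycolysis and the pyruvate list, 10 purine genes higher in place of 6 and 5 other carbohydrate genes higher in place of 1. It also gave 11 other amino acid genes lower in place of 5, and 5 pyrimidine genes lower in place of 3. Further lower counts were 12 in place of 8 in other carbohydrates and 2 in place of 1 in glycolysis. They were 2 in place of 0 in ATP synthase and 4 in place of 2 in the cell wall list. In the menaquinone and haem list 2 genes were then higher in place of 0.

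**Figure D1:**
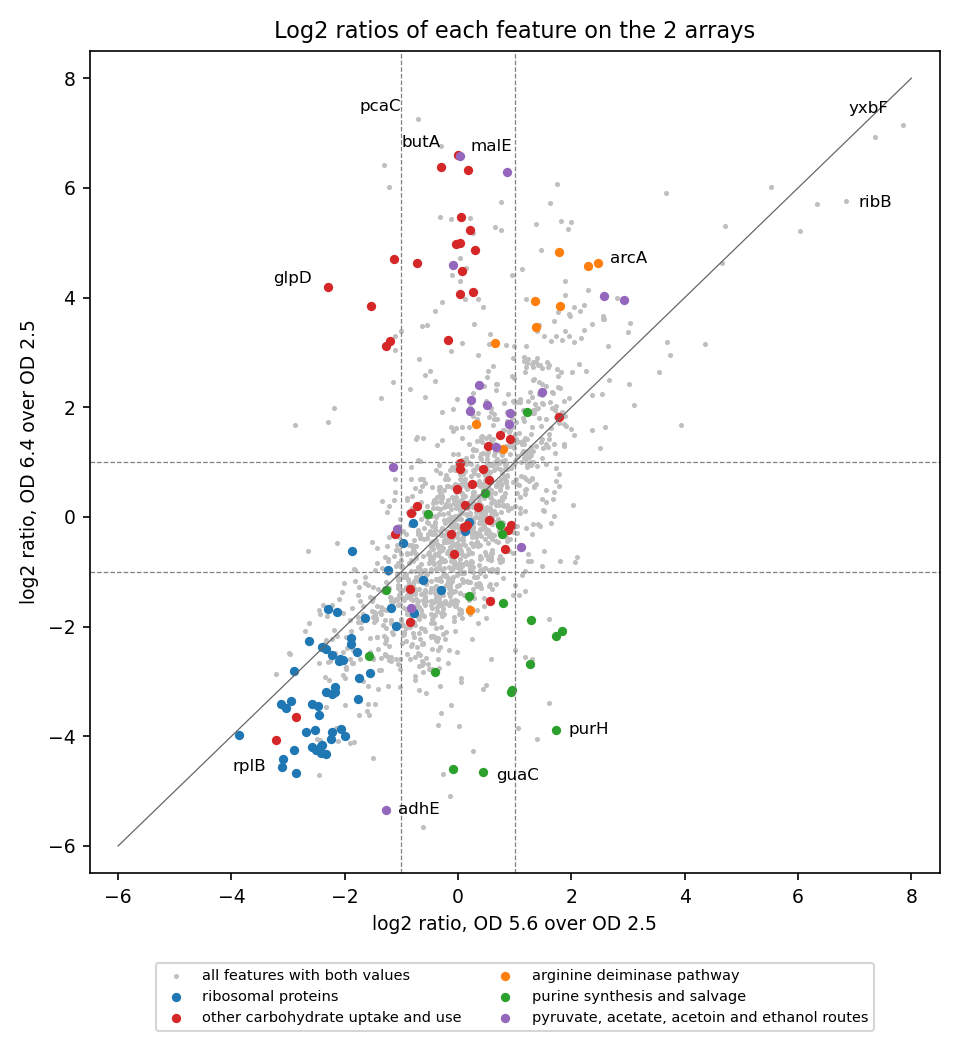
Each point is 1 feature, with its log2 ratio at OD 5.6 on the horizontal axis and at OD 6.4 on the vertical axis, both over OD 2.5. Colours mark 5 fixed gene lists, dashed lines the 2-fold size, and the solid line equal values. Ribosomal protein genes lie low on both arrays, many carbohydrate genes such as malE (-0.004 and 6.59) are high on the second array alone, and purH lies at 1.73 and -3.89.

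The second comparison set OD 6.4 against OD 2.5. Of the fixed lists, lactose and galactose use (median 3.91 over 4 features) and the arginine deiminase pathway (3.65) had the highest medians, followed by the pyruvate routes and oxidative stress (both 1.99) and other carbohydrates (1.42). Ribosomal proteins (-3.10) and purines (-2.08) had the lowest. In all, 396 of 1658 features (23.9%) were at least 2-fold higher and 532 (32.1%) at least 2-fold lower. The excess of lower features was absent with the array centred on its median (456 higher and 454 lower) and turned when both arrays were also scaled to one median absolute deviation (388 higher and 356 lower). Among the highest 10 were pcaC (7.25), yxbF (7.14), yufA (6.93), yxbD (6.92), recF (6.83), yreA (6.77), malE (6.59), butA (6.59) and rmeD (6.41). The features yufA and recF had no value on the OD 5.6 array. The lowest 10 were yriD (-5.66), adhE (-5.34), pbuX (-5.09), yvdD (-4.71), glnP (-4.68), rplC (-4.67), guaC (-4.65), xpt (-4.60), rplB (-4.55) and rplW (-4.42).

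Of 51 genes for other carbohydrates, 27 were at least 2-fold higher at OD 6.4 and 5 at least 2-fold lower (median 1.42, interval 0.51 to 3.22), above all 10000 random lists. The highest were malE at 6.59, for the binding protein of maltose uptake, and ptcB at 6.38, a subunit of the cellobiose and glucose phosphotransferase system. The lowest were ptnAB at -4.07 and ptnC at -3.64, so phosphotransferase genes stood at both ends of the list. In the lactose and galactose list lacR (4.52) and lacC (3.31) were at least 2-fold higher and galK stood at 0.80. That list matched only 4 features under its fixed names. Another 9 features carry lac names with the prefix p-, whose meaning the sources used here do not give, and without p-lacR they lay between -1.05 and 0.39. The feature p-lacR stood at -1.36, against 4.52 for lacR. These features were looked up after the data were seen, and with them the median of the list at OD 6.4 is 0.25 in place of 3.91.

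Of 18 genes for the fates of pyruvate, 13 were at least 2-fold higher at OD 6.4 and 2 at least 2-fold lower (median 1.99, interval 1.09 to 3.18). The highest were butA (6.59) and butB (6.29), whose products act on acetoin and butanediol. The acetolactate synthase gene als stood at 2.41, aldB at 1.90, the pyruvate dehydrogenase gene pdhA at 2.14 and pfl at 4.02. The lowest were adhE, for the aldehyde-alcohol dehydrogenase of ethanol formation, at -5.34, and aldC at -1.67. The other adh gene of the list, adhA, stood at 4.60. In glycolysis 5 of 13 genes were at least 2-fold lower and 2 at least 2-fold higher, with ldh at -1.42, fbaA at -1.67 and enoB at 2.53. ATP synthase genes had a median of -0.97, with 2 of 7 at least 2-fold lower, atpE at -1.503 and atpG at -1.40. Of the respiration list 4 of 9 genes were at least 2-fold higher, with qor at 3.12, noxA at 2.56 and noxE at 2.43, and 1, noxB at -1.42, at least 2-fold lower, and cydA and cydB stood at 0.084 and 0.057. In the menaquinone and haem list 2 of 14 genes were at least 2-fold higher and 2 at least 2-fold lower, the lowest being hemH, for ferrochelatase, at -3.79.

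The arginine deiminase list had 9 of 10 genes at least 2-fold higher (median 3.65, interval 1.70 to 4.57), the regulator genes argR and ahrC among them. Its highest members were arcC2 at 4.83, a carbamate kinase gene, and arcA at 4.64, arcB stood at 4.57 and arcD1 at 3.46, and the remaining member arcC3 was at -1.69. In the list of arginine, glutamate and glutamine synthesis 7 of 11 genes were at least 2-fold lower and 3 at least 2-fold higher (median -1.38, interval -3.40 to 2.71). The lowest were glnP (-4.68), for a glutamine transporter, and glnR (-3.86), for the regulator of nitrogen genes, and the highest were argD (3.41) and argG (2.97). Purine genes had 14 of 19 members at least 2-fold lower and 1, deoD at 1.91, at least 2-fold higher (median -2.08, interval -2.83 to -1.33). The lowest were guaC (-4.65), for GMP reductase, and xpt (-4.60), for xanthine phosphoribosyltransferase. Pyrimidine genes had 8 of 13 at least 2-fold lower, with pyrC and pyrE both at -3.42, and 2 at least 2-fold higher, pdp and cdd, both at 1.63. Of 46 other amino acid genes, 25 were at least 2-fold lower and 3 at least 2-fold higher (median -1.20), with hom at -2.71 and proC at 1.30. Peptide uptake and peptidase genes had 12 of 26 at least 2-fold lower, with dtpT at -4.09 and oppA at -1.10, and 3 at least 2-fold higher, led by pepP at 2.77.

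Ribosomal protein genes were at least 2-fold lower at OD 6.4 in 49 of 55 cases and at least 2-fold higher in none (median -3.10, interval -3.42 to -2.52), with rplC at -4.67 and rplB at -4.55. The RNA polymerase list had 8 of 10 genes at least 2-fold lower (median -1.98), and rpoD stood at 0.95. Translation factors and tRNA synthetases had 17 of 30 at least 2-fold lower, tyrS at -3.62 and prfA at -3.61 being the lowest, and 5 at least 2-fold higher, pheS at 3.15 being the highest. Fatty acid synthesis had 9 of 15 at least 2-fold lower (median -1.28, interval -1.45 to -0.97), or 8 of 15 with the array centred (median -1.04) and 4 of 15 with both arrays also scaled to one median absolute deviation (median -0.82). Oxidative stress genes had 8 of 11 at least 2-fold higher and none at least 2-fold lower (median 1.99, interval 0.798 to 3.12), with gpo, for glutathione peroxidase, at 3.82, gshR at 3.75 and sodA at 3.12. In the heat shock list 5 of 14 were at least 2-fold higher, led by hslB (5.39) and clpE (2.10), with groEL at 0.95 and dnaK at 0.58, and none was at least 2-fold lower. The cell wall list had 11 of 27 at least 2-fold lower, with dltB at -2.60 and dltC at -2.59, genes for adding D-alanine to teichoic acids, and 3 at least 2-fold higher, acmC at 2.66 among them. DNA replication and cell division genes had 10 of 32 at least 2-fold lower and 1, polA at 1.81, at least 2-fold higher. Metal uptake genes had a median of -0.27 as deposited and -0.026 after centring, with zitP at -1.92 and copB at 1.78. With both arrays centred and scaled to one median absolute deviation fewer genes were at least 2-fold lower, in part by the centring. The lower counts were then 1 in place of 5 in glycolysis, where 2 were higher with either, 15 in place of 25 in other amino acid synthesis and 10 in place of 17 in translation. They were 6 in place of 11 in the cell wall list, 6 in place of 10 in DNA replication and 0 in place of 2 in ATP synthase (median -0.58). With centring alone these 6 counts were 4, 21, 14, 9, 7 and 2. Centring alone also gave 5 menaquinone and haem genes at least 2-fold higher in place of 2.

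**Figure D2:**
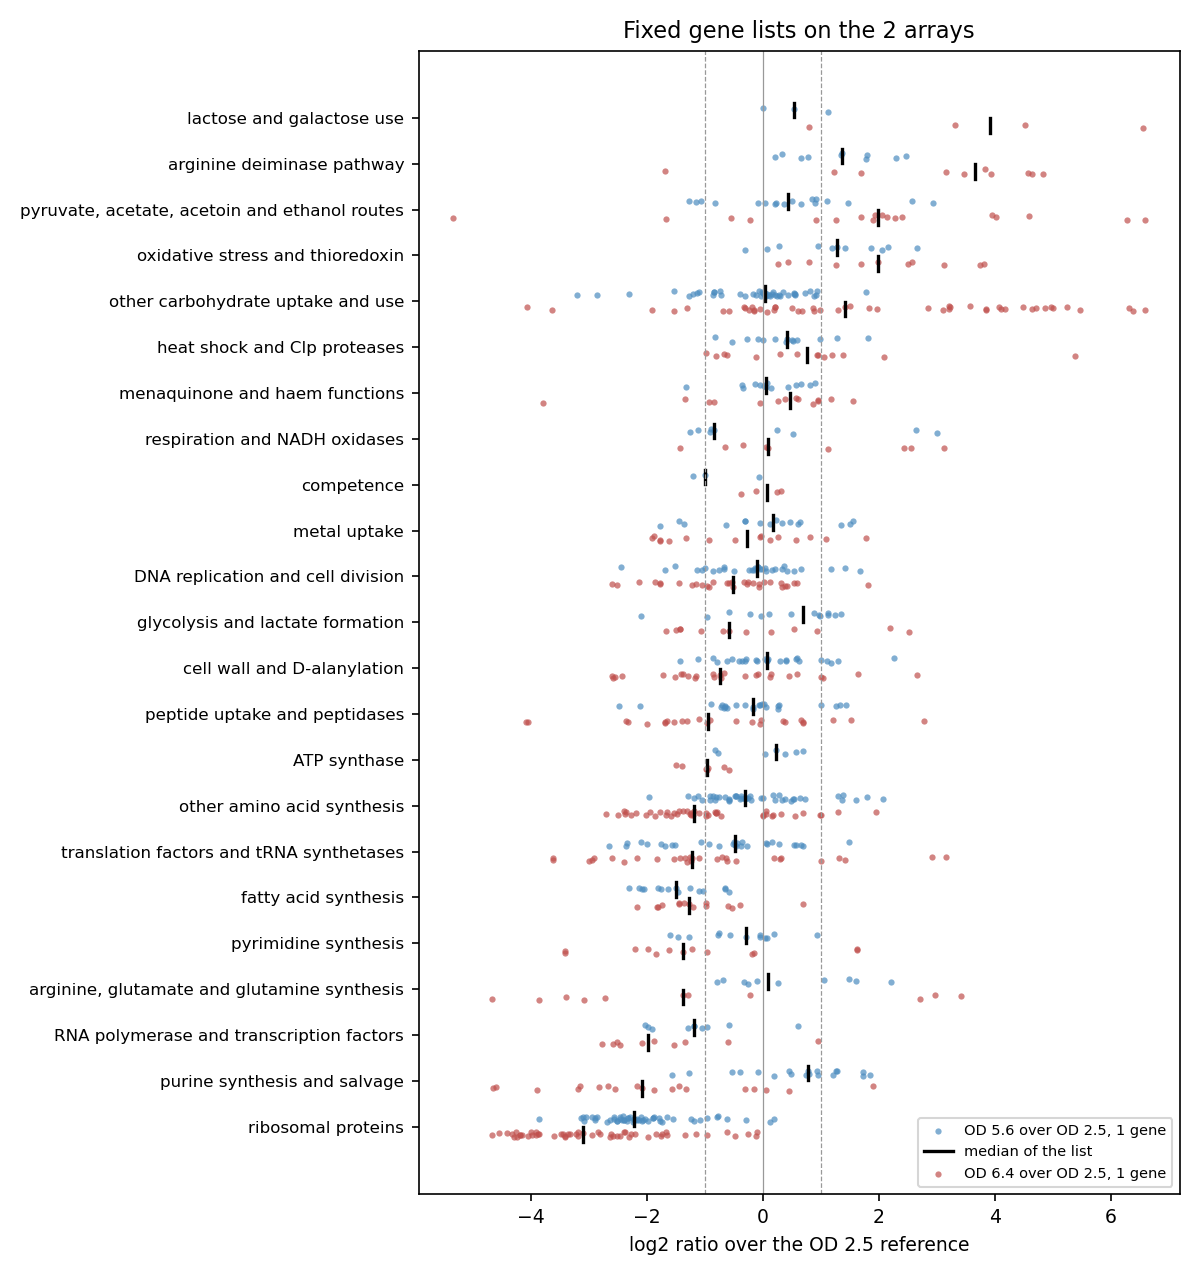
Each point is 1 gene of a fixed list, with its log2 ratio over OD 2.5 on the horizontal axis, blue for the OD 5.6 array and red for the OD 6.4 array. Black bars are list medians, and lists with at least 3 values on the OD 6.4 array are shown in order of their OD 6.4 median. The purine list stands at 0.77 and -2.08 and the ribosomal protein list at -2.23 and -3.10.

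The third comparison set OD 6.4 against OD 5.6 by the difference of the log2 ratios. Of the lists with at least 10 genes, the arginine deiminase pathway had the highest median difference as deposited (2.13) and purines the lowest (-2.43). When both arrays were centred and scaled to one median absolute deviation, fatty acid synthesis (1.44) and other carbohydrates (1.09) lay above arginine deiminase (0.94). As deposited, 223 of 1611 features were at least 2-fold higher at OD 6.4 and 383 at least 2-fold lower, so 36.8% of those past the size were higher. With each array centred on its median there were 297 higher and 272 lower, and the share was 52.2%. With the arrays also scaled to one median absolute deviation there were 273 higher and 225 lower, and the share was 54.8%. The median difference of all features was -0.28, and values below are to be read against it.

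Among the 10 features with the largest positive difference were pcaC (7.97), rmeD (7.71), yreB (7.22), yreA (7.06), ptcB (6.68), malE (6.60), butA (6.56), glpD (6.49), for glycerol-3-phosphate oxidation, and malG (6.15). The 10 with the largest negative difference were purH (-5.62), yphF (-5.44), guaC (-5.09), yriD (-5.04), glnA (-5.00), for glutamine synthetase, pbuX (-4.94), a xanthine permease gene, glnR (-4.91), yjgC (-4.53), xpt (-4.51) and glnP (-4.42). Of 46 other carbohydrate genes with both values, 18 were at least 2-fold higher at OD 6.4 and 5 at least 2-fold lower, or 25 and 2 with the arrays centred. Of 10 arginine deiminase genes 8 were at least 2-fold higher and 1 at least 2-fold lower (median 2.13, interval 1.24 to 2.51), and with the arrays scaled to one median absolute deviation 5 were at least 2-fold higher (median 0.94). In the pyruvate list 10 of 18 were at least 2-fold higher and 2 at least 2-fold lower (median 1.24, or 0.79 with that scaling). Its gene adhE stood at -4.06 and adhA at 4.69. None of the 19 purine genes was at least 2-fold higher and 13 were at least 2-fold lower (median -2.43, interval -3.94 to -0.975). Of 7 ATP synthase genes 4 were at least 2-fold lower, the list median being -1.21, and all 7 lay below 0 as deposited. With the arrays centred 2 of 7 were at least 2-fold lower (median -0.96), and with that scaling 3 of 7 (median -0.88). The ribosomal protein genes differed by a median of -0.87, with 22 of 55 at least 2-fold lower and 1 at least 2-fold higher, and this direction turned to 0.77 when the arrays were scaled to one median absolute deviation, with 18 at least 2-fold higher and none at least 2-fold lower. The same scaling turned the medians of the translation list (from -0.51 to 0.32) and the RNA polymerase list (from -0.55 to 0.54). The fatty acid list had a median difference of 0.43, with 1 of 15 at least 2-fold higher and none at least 2-fold lower, and with that scaling the median was 1.44 and 12 of 15 were at least 2-fold higher.

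Across the 1611 features with both values the 2 arrays had a Pearson r of 0.64 and a Spearman rho of 0.66. These are correlations across genes, which are not independent replicates. For 2 unchanged samples measured against 1 shared reference with equal noise in all samples, simulation gave a mean r of 0.50 (0.44 to 0.57 over 1000 simulated pairs). That value is set by the equal noise, while the SD over features was 1.17 at OD 5.6 and 1.98 at OD 6.4. The r of 0.64 can therefore not be judged against it. The covariance of the arrays was 1.45, and no simulated covariance is set beside it because the size of the noise is unknown. The features at least 2-fold higher on both arrays numbered 189, against 61.4 for independent lists of 265 and 373. Those at least 2-fold lower on both numbered 210, against 87.5 for independent lists of 265 and 532. The single reference sample cannot be split, so part of the excess may come from it. The later sample carried Cy5 on both arrays, so a dye bias of single genes would enter both ratios alike. It could also add to the excess and to r. There were 16 features at least 2-fold higher at OD 5.6 and at least 2-fold lower at OD 6.4, and 15 the other way.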

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

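All tests in this part were chosen after the results were seen. No difference between the arrays was tested, since each density has 1 array.

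A group of 16 features was at least 2-fold higher at OD 5.6 and at least 2-fold lower at OD 6.4, and a group of 15 was the reverse, so the densities stood on opposite sides of OD 2.5. The first group held purD, purE, purF, purH and purK, the teichoic acid genes dltA, dltB and dltD, the glutamine genes glnA and glnR, and metB2, pfk, fhs, p-lacR, yciA and yphF. The second held glpD, glpF2, ptcA, ptbA, bglH, rmeD, yreB, yueF, yedE, yedF, yeeA, ypcB, ypdA, ypdB and ypdC. The purine list as a whole had a median of 0.77 at OD 5.6 and -2.08 at OD 6.4. All 8 measured genes from purD to purN lay between 0.79 and 1.84 at OD 5.6 and between -3.89 and -1.57 at OD 6.4. The glycolysis list had medians of 0.69 and -0.58, again on opposite sides. Its bootstrap intervals over genes both held 0 (-0.13 to 1.05 at OD 5.6 and -1.42 to 0.545 at OD 6.4). Centring the array brought its OD 6.4 median to -0.34. These differences were not tested.

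The OD 5.6 array had no value for 47 features, which therefore stand outside the difference of the arrays. Of these, 23 were at least 2-fold higher at OD 6.4 and none was at least 2-fold lower, a share of 48.9% against 23.2% among features with both values. These 23 include yufA (6.93), recF (6.83), ynjD (6.02), ygjD (5.71), glpK (3.58), lacC (3.31), ptcC (3.85) and bglA (3.22).

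The ratios were spread more widely at OD 6.4 than at OD 5.6, with a median absolute deviation 1.72 times as large (95% bootstrap interval 1.578 to 1.879). A single scale factor as the only difference between the arrays is argued against. Compared were 5 lists with at least 3 genes on both arrays and a median at least 2-fold from the array's at OD 5.6. In 3 of them the ratio of medians had an interval over genes that left out 1.72. These were fatty acid synthesis (0.69), ribosomal proteins (1.28) and arginine deiminase (2.88). A scale difference together with changes of these lists stays open, since such changes would move the ratios with or without it. The distance from the median to the lower quartile was 1.63 times as large (interval 1.48 to 1.85), so the widening was not confined to the upper side. To the upper quartile it was 1.87 times as large (interval 1.59 to 2.08). In the tails the sides differed more, with 2.28 to the 95th percentile and 1.28 to the 5th, both without an interval. Weak reference signal, which inflates ratios upwards, makes no prediction below the median, so the values on the lower side do not decide on it. For features above the median it stays open, since without intensities no table decides, and of the 132 features at 3 or more at OD 6.4, 12.9% had no OD 5.6 value against 1.97% of the others. A wider response of the cells at the higher density also stays open and untested.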

How the results depend on the processing

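No direction of a list with a median of at least 1 in size was reversed by centring, by scaling to one median absolute deviation, by list means, by features on both arrays or by the added p- features. With array medians of 0.014 and -0.239, centring and scaling could not reverse such a list on 1 array, so this says little for them. In the difference scaling could do so. There it turned the smaller medians of ribosomal proteins (-0.87 to 0.77), translation and RNA polymerase. The counts moved by over 1.5 times mainly with the threshold, which by its construction sets them. At 1.5-fold, 439 features were higher and 444 lower at OD 5.6, and for OD 6.4 against OD 5.6 there were 365 higher and 593 lower. At 3-fold, 112 were higher and 129 lower at OD 5.6, 328 lower at OD 6.4, and 138 higher and 163 lower in the difference. Scaling to one median absolute deviation, which includes centring, left 225 lower in the difference in place of 383, and centring alone left 272. The lactose and galactose list moved from 3.91 to 0.25 at OD 6.4 with the p- features, since the added features outnumber the 4 of the list. In the difference the same features took that list from 3.39 to 0.32. Of 142 alternatives for the main results, 18 moved, counts by over 1.5 times and list medians out of their bootstrap interval. That interval is wide for a list of few genes, so the value of 0.32 is not among the 18. Part of the 142 could not move at all. Examples are the averaging of same-named features and, for the difference counts, the restriction to features on both arrays. The 18 of 142 is therefore no measure of stability. Scaling of the lists to one median absolute deviation was added after the data were seen. With it the ribosomal protein medians were -3.05 at OD 5.6 and -2.26 at OD 6.4, the fatty acid medians -2.06 and -0.82, and the differences of the arginine deiminase and pyruvate lists 0.94 and 0.79. Centring is part of this setting, and alone it gave -2.24 and -2.86 for ribosomal proteins, -1.51 and -1.04 for fatty acids, and 2.39 and 1.49 for the differences of the arginine deiminase and pyruvate lists. The full scaling, centring included, brought the OD 6.4 medians of other amino acid synthesis from -1.20 to -0.76 and of pyrimidines from -1.37 to -0.89. It brought those of translation from -1.22 to -0.78 and of arginine, glutamate and glutamine synthesis from -1.38 to -0.90. All 4 then lay under 2-fold. Centring alone already gave -0.96, -1.13, -0.99 and -1.14 for these 4 lists. The correlation of the arrays was 0.66 as Spearman's rho and 0.62 without the largest 5% of features. No feature name was repeated, so the averaging of same-named features moved nothing. Runs in the order of the reference annotation were not run. Against random features, 6, 10 and 9 of 24 lists lay outside percentiles 1 to 99 at OD 5.6, at OD 6.4 and in the difference, and against alphabetical runs, which keep related genes together, 2, 3 and 7 did. The 2 at OD 5.6 were ribosomal proteins and arginine deiminase, and at OD 6.4 the other carbohydrate genes joined them. No paired analysis was possible because each density has 1 array, and no replicate could be left out. Without intensities, signal over background limits every ratio to an unknown extent.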

Other observations

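Of the tests in this part, those of the ratio direction and of the chromosome trend were fixed before the data were examined, and that of the repeated value was chosen after it was seen. The genes in the next paragraph were also chosen after their values were seen.

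Of 5 riboflavin features, ribA, ribB, ribG and ribH stood at 4.66 to 6.85 at OD 5.6 and 4.63 to 5.76 at OD 6.4, and ribC at -1.68 and -1.62. Of the glycogen stem glg, 3 of 4 features were at least 2-fold higher at OD 5.6 and all 4 at OD 6.4, where glgC, for ADP-glucose pyrophosphorylase, stood at 4.05. The maltose features malE, malF and malG, which belong to the list of other carbohydrates, and malQ, which does not, had a median of 0.03 at OD 5.6 and 5.89 at OD 6.4. On the low side at OD 6.4 were the phosphonate genes phnA, phnB, phnC and phnE (median -3.08), the polyamine uptake genes potA, potB, potC and potD (median -2.43) and the osmoprotectant uptake genes busAA and busAB (-2.88 and -3.08), with busR at -1.42. The features choQ and choS stood at 2.46 and 2.42 at OD 6.4. Of the fixed lists not described so far, competence had 4 values at OD 6.4, between -0.37 and 0.31, and cspD and cspE of the cold shock list stood at -0.10 and 0.90 there. Of the ribosomal RNA features, rRNA-16S stood at 0.46 at OD 5.6 and 0.79 at OD 6.4, rRNA-5S at -0.89 and 0.10, and rRNA-23S at 0.91 at OD 6.4 with no OD 5.6 value.

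The direction of the deposited ratios was checked with the ribosomal protein genes, which bacteria are known to transcribe less as growth slows. If the ratios ran as OD 2.5 over the later sample, these 55 genes would lie above the array's median. They lay 2.24 below it at OD 5.6 (a value of -2.24) and 2.86 below it at OD 6.4 (-2.86), which argues against that reading on this background knowledge. A trend of the ratios with distance from the replication origin, which lower gene dosage at the origin in slower cells could give, cannot be decided here because 18.6% of the features matched a gene with a known position.

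On the OD 6.4 array the value 0.687 occurs 16 times, while the next most frequent value occurs 5 times. In 1000 sets drawn from smoothed values the highest repeat was 6. Of the 16 features, 6 (37.5%) had no value at OD 5.6 and 0 held its most repeated value, and of the other 1642, 2.86% had no value or held it. A candidate explanation is a fixed floor given to both channels of weak features, whose ratio the normalization then moved by one amount. It stays open, since the most repeated value at OD 5.6 (0.261, 7 times) was within the 7 that drawn sets reached. Both values lie under 2-fold, so leaving out the features at either could move the counts of each array at 2-fold only little. In the difference a feature at 0.687 can pass 2-fold, as acpD of the fatty acid list did (1.34). Leaving the features out gave 218 higher in place of 223 and 382 lower in place of 383 there. None of these counts moved by over 1.5 times, which does not bear on a floor.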
